A study of Mus musculus with 12 samples.

How the data were processed

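Total RNA came from lung homogenate of 12 C57Bl/6 mice aged 10 weeks, 3 in each of 4 groups: baseline male, ventilated male, baseline female and ventilated female. Per the labels, baseline mice were intact, and ventilated mice received 2.5 h of positive pressure at 15 cmH2O without end-expiratory pressure, at 100 breaths per min and an inspired oxygen fraction of 0.21. RNA was extracted with Trizol and a column kit, and 100 ng were amplified and biotin-labelled for Affymetrix arrays, per the labels. The deposited table gives a log2 expression value for each of 24654 probe sets in each array. The submitters' processing notes name RMA, which corrects background, normalizes between arrays and summarises probes, and limma. Their versions, and how the deposited probe sets were chosen, are not given in the sources used here. That the values are on a log2 scale was inferred from their range, 2.49 to 13.3, and the array medians of 5.88 to 5.95. The labels give no batch, array date or time of day, so none could be modelled, and the number of arrays limits the precision.

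Probe sets were joined to gene symbols through the platform's probe annotation. Of 24654 probe sets, 21921 had 1 symbol, 817 several and 1916 none, and those without a single symbol, 2733, were left out of the gene tests. Gene identifiers of 21829 probe sets were found in the RefSeq gene table, and 0 of their symbols differed. Where a gene had several probe sets (302 genes), the one with the highest mean signal was used, which left 21506 genes. No filter on dim genes was applied. All 12 columns of the table were assigned to their group by the sample titles.

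R 4.3.3 and limma 3.58.1 fitted a mean per group to all 12 arrays, with 8 residual degrees of freedom and 5.52 prior degrees of freedom from empirical Bayes with default settings. The contrasts were ventilated minus baseline in males, in females and as the mean of both sexes, the interaction (female minus male ventilation change), and female minus male at baseline and after ventilation. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over 21506 genes within each contrast, and genes with an adjusted p under 0.05 are said to have changed. The fit used no block for the replicate number. The changes of the 2 sexes were compared by their correlation across genes. Means of marker genes per array were compared by exact permutation tests of the group labels, whose smallest two-sided p is 0.1 for 3 against 3 mice.

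Before the data were examined, 60 gene lists were fixed, covering responses of lung to stress, inflammation, stretch and injury, sex-linked and hormone-responsive genes, markers of lung cell types, markers of other tissues and technical groups. Of their 1068 genes 930 were measured, and 59 lists had at least 5 measured members. Lists were tested with camera of limma at its preset correlation of 0.01, which compares the members of a list with all other genes, with p-values adjusted over the 59 lists of a contrast. An estimated correlation per list and fry, which tests whether the members move on balance in 1 direction, served as alternatives. Counts of changed members are given over all genes and adjusted over the list alone. The contrasts, the alternatives and the rule for naming genes were also fixed then. The rule took up to 12 genes with the largest increase and up to 8 with the largest decrease among those that passed, with groups that did not overlap where 2 groups were compared. Predicted and clone-named genes, microRNA, nucleolar and nuclear RNA genes, immune receptor variable segments and olfactory and vomeronasal receptors were counted only. With fewer than 5 genes passing in a direction, the 5 with the lowest p were named as not passing. It allowed the 4 members of a list with the lowest p, and always took a set of cytokine, stress, hormone receptor and sex-linked genes, of which those without an annotated probe set, such as Ddx3y, were not analysed here.

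The alternatives were leaving out genes in the lowest 25% of mean signal, the mean of all probe sets of a gene, testing every probe set, empirical Bayes with trend and robust fitting, array weights, a block for the replicate number, quantile normalization, median centring, a minimum change of 2-fold, only the 2 groups compared, and leaving out each array in turn. Leaving out baseline male 3 and baseline female 2 together was added after the data were seen. Groups left with 2 arrays shared the spread estimated over all groups. The fit was tested on simulated data of the same size, in which 200 genes had been changed alike. At log2 changes of 0.5, 1 and 2, 41%, 92.5% and 100% of them were found for ventilation in males.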

Results

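Gene expression was measured in whole-lung homogenate of C57Bl/6 mice aged 10 weeks on 12 Affymetrix Mouse Gene 2.0 ST arrays, 1 per mouse. The mice formed 4 groups of 3: males and females, each intact (baseline) or ventilated. Ventilation was 2.5 h of air at a peak of 15 cmH2O, without end-expiratory pressure. With no sham group, ventilation cannot be told apart from handling and time. The series asks whether the sexes differ in their susceptibility to ventilator-induced lung injury, the damage that stretch by a ventilator does to the lung. Each array gave a log2 signal (2.49 to 13.3, medians 5.88 to 5.95) for 24654 probe sets, which hold 21506 genes with a single symbol. Genes given as the largest changes between 2 groups are those whose arrays did not overlap. Where 2 p are given for a gene list, the first is at the preset correlation and the second by estimated correlation. Near background, which Y-linked genes put at 3.65 to 4.04 in baseline females, lay Slc7a11 and Il6 at baseline, and after ventilation Ifi208, Cr2 in males and Cyp4a14 and Mup20 in females, so their changes are lower bounds in size. All changes below are log2 differences ± SE from limma with n = 3 mice per group, and all tests are two-sided.

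Arrays of the same group correlated at r = 0.987 to 0.994 and arrays of different groups at 0.974 to 0.991, across genes, which are not independent replicates. The first principal component, 33.1% of the variance, placed the 6 baseline arrays between -24.9 and -4.98 and the 6 ventilated arrays between 0.258 and 30.4. The second, 17.8%, placed the 6 male arrays between -21.9 and -0.877 and the 6 female arrays between 4.41 and 17.4. A pair of arrays stood apart. Baseline male 3 lay at -28.8 on the third component (12.1%), where the other 11 arrays lay between -11.6 and 14.6. Its heat shock genes averaged 9.09 against 7.93 and 8.08 in the other baseline males, and its markers of ciliated cells 8.52 against 7.74 and 8.05. Its cardiac markers averaged 7.83 against 5.86 and 6.10, below ventilated female 1 at 8.20, and the baseline females had 6.80 to 7.53. Baseline female 2 had the highest signal of Alb, the albumin of liver, at 11.4, where the other 11 arrays lay between 5.71 and 9.01.

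In males, ventilation raised Slc7a11, the cystine importer that feeds glutathione synthesis, at least 17.4-fold (4.12 ± 0.23, adjusted p = 1.47e-06). The vasoactive peptide Adm rose 8.43-fold (3.08 ± 0.21), the inducible prostaglandin synthase Ptgs2 6.9-fold (2.79 ± 0.26) and the heme oxygenase Hmox1 6.15-fold (2.62 ± 0.25). The cell cycle inhibitor Cdkn1a rose 6.71-fold (2.75 ± 0.20) and the TWEAK receptor Tnfrsf12a 6.83-fold (2.77 ± 0.23). The clock output factor Dbp (-2.73 ± 0.39), the clock gene Per3 (-2.24 ± 0.29), the endothelial gene Tmem100 (-1.78 ± 0.12) and the B cell gene Ms4a1 (-1.58 ± 0.22) fell. The remaining large rises were Saa3 (2.62 ± 0.31), Atf3 (2.60 ± 0.38), Pdk4 (2.29 ± 0.29), Mt2 (2.26 ± 0.20), Plk3 (2.15 ± 0.23) and Thbs1 (2.12 ± 0.22), and the remaining large falls Lrrn3 (-1.57 ± 0.15), Olfml1 (-1.54 ± 0.23), Ifi208 (-1.54 ± 0.36) and Bank1 (-1.53 ± 0.21). At an adjusted p under 0.05, 1929 of 21506 genes changed, 1165 upward and 764 downward, of which 175 at least 2-fold. In 1904 of them the 3 ventilated and the 3 baseline males did not overlap, as for 26.2% of all genes against the 10% that chance gives. The number of genes was 1037 without baseline male 2, 1223 without ventilated male 1 and 1077 without ventilated male 2. Leaving out 1 array ended the call of Ifi208 (baseline males 1 and 2 or ventilated male 3, adjusted p = 0.0538 to 0.0653).

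Genes of the first stress and stimulus responses rose together in males. Among immediate-early genes, transcription factors and phosphatases induced first by many stimuli, 17 of 35 members rose and 1 fell (20 and 1 adjusted over the list alone), with median 0.65, adjusted p = 6.82e-11 and 0.35 by estimated correlation. Gadd45g (2.02 ± 0.21), the growth regulator Myc (1.98 ± 0.22), Maff (1.44 ± 0.18) and the phosphatase Dusp4 (0.73 ± 0.09) had the lowest p. Fos (0.54 ± 0.33) and Egr1 (1.14 ± 0.43), with adjusted p = 0.121 to 0.388, did not pass. Egr1 passed without ventilated male 3 (adjusted p = 0.0369). Glucocorticoid-responsive genes rose (median 0.57, adjusted p = 1.46e-10 and 0.0568). 13 of 23 members rose and 0 fell (15 and 1 over the list alone), among them the chaperone Fkbp5 (1.59 ± 0.19). Nrf2 and oxidant defence genes rose (median 0.29, adjusted p = 3.03e-06 and 0.201). 9 of 20 members rose and 0 fell (9 and 2 over the list alone), with the glutathione-making enzyme Gclc (1.69 ± 0.15) beside Slc7a11, Mt2 and Hmox1. In the unfolded protein and integrated stress response, 10 of 20 members rose and 0 fell (11 and 0 over the list alone), with median 0.41, adjusted p = 3.0e-08 and 0.266. It held Atf4 (1.13 ± 0.12), Sesn2 (1.60 ± 0.19), Asns (1.09 ± 0.14) and Atf5 (0.68 ± 0.10). Of the p53 and senescence genes 6 of 19 members rose and 0 fell (7 and 0 over the list alone), with median 0.26, adjusted p = 2.52e-05 and 0.0667, and Aen (0.61 ± 0.10) was among them. Of the apoptosis and pyroptosis genes 7 of 19 members rose and 0 fell (7 and 0 over the list alone), with median 0.17, adjusted p = 0.000165 and 0.0667. The inflammatory caspase Casp4 (0.80 ± 0.10), the survival factor Bcl2l1 (0.73 ± 0.14) and the necroptosis effector Mlkl (0.63 ± 0.14) rose. Heat shock genes rose (median 0.42, adjusted p = 0.000353 and 0.484). 5 of 15 members rose and 0 fell (6 and 0 over the list alone), led by Hspb8 (1.20 ± 0.20). Their mean stood at 9.09 in baseline male 3. Hypoxia and glycolysis genes rose (median 0.14, adjusted p = 0.0161 and 0.35). 3 of 18 members rose and 0 fell (4 and 1 over the list alone), with the glucose transporter Slc2a1 (1.01 ± 0.16) beside Adm. The call ended when a single array was left out for the hypoxia list (ventilated male 3, adjusted p = 0.0675). Medians moved over 1.5-fold without 1 array for the heat shock list (baseline males 1 and 3 or ventilated male 3, 0.28 to 0.82).

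Inflammatory genes of males rose in part. NF-kB targets rose (median 0.43, adjusted p = 6.2e-08 and 0.0568 by estimated correlation). 13 of 23 members rose and 1 fell (14 and 1 adjusted over the list alone), with Nfkb2 (1.00 ± 0.10), Bcl3 (1.49 ± 0.17) and Tnip1 (0.85 ± 0.11) beside Ptgs2. Cytokines and their receptors rose (median 0.29, adjusted p = 2.81e-05 and 0.0929). 5 of 22 members rose and 0 fell (8 and 0 over the list alone), with the decoy receptor Il1r2 (1.48 ± 0.16), Tnfsf9 (0.92 ± 0.12), the EGF-like ligand Hbegf (1.99 ± 0.29) and Il4ra (0.69 ± 0.12). The classic cytokines did not pass: Il6 (0.44 ± 0.15), Il1b (0.14 ± 0.31) and Tnf (0.17 ± 0.24), with adjusted p = 0.0992 to 0.857. Il6 passed without ventilated male 1 (adjusted p = 0.0261). Chemokines as a list did not pass (median 0.12, adjusted p = 0.254), while 4 of 27 members rose and 0 fell (6 and 1 over the list alone). Cxcl16 (0.76 ± 0.10) and the neutrophil attractant Cxcl1 (0.84 ± 0.21, adjusted p = 0.024) rose, and Cxcl2 (-0.26 ± 0.17) and Ccl2 (0.27 ± 0.18), with adjusted p = 0.412 to 0.442, did not pass. Neutrophil markers rose (median 0.48, adjusted p = 7.38e-06 and 0.35). 5 of 23 members rose and 0 fell (10 and 0 over the list alone), with Il1f9 (1.62 ± 0.25), Clec4d (0.89 ± 0.14) and Mmp8 (1.66 ± 0.29). Genes of coagulation and fibrinolysis rose (median 0.39, adjusted p = 4.5e-05 and 0.0568). 7 of 17 members rose and 0 fell (9 and 0 over the list alone), with tissue factor F3 (2.03 ± 0.25), F10 (0.89 ± 0.12) and the urokinase receptor Plaur (1.497 ± 0.22). A single omitted array ended the call of Cxcl1 (baseline males 2 and 3 or any ventilated male, adjusted p = 0.0541 to 0.0859). Without 1 array medians moved over 1.5-fold for the neutrophil list (ventilated males 1 and 3, 0.29 to 0.73).

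Matrix, junction and mechanical response genes also moved in males. Extracellular matrix genes rose (median 0.24, adjusted p = 1.79e-05 and 0.201 by estimated correlation). 11 of 30 members rose and 1 fell (13 and 1 adjusted over the list alone), with the collagen cross-linker Lox (1.82 ± 0.16), Tnc (1.67 ± 0.19) and Timp1 (0.68 ± 0.09). Targets of YAP, TAZ and SRF, which answer to stretch of the cytoskeleton, rose (median 0.21, adjusted p = 0.0124 and 0.446). 4 of 24 members rose and 1 fell (7 and 1 over the list alone). Genes of the nuclear lamina and of mechanosensing did not pass as a list (median 0.09, adjusted p = 0.172). The lamin gene Lmna rose (0.56 ± 0.12, adjusted p = 0.00987). Junction genes rose (median 0.18, adjusted p = 0.0131 and 0.35). 5 of 18 members rose and 0 fell (7 and 0 over the list alone), led by Cldn4 (1.42 ± 0.24). Fluid transport genes rose (median 0.18, adjusted p = 0.0131 and 0.35). 4 of 15 members rose and 0 fell (4 and 0 over the list alone), with the kinase Sgk1 (0.57 ± 0.10), the chloride channel Cftr (0.86 ± 0.17) and Nedd4l (0.47 ± 0.09). Androgen-responsive genes rose (median 0.08, adjusted p = 0.0394 and 0.35). 4 of 15 members rose and 0 fell (6 and 0 over the list alone). Estrogen-responsive genes did not pass (median -0.04, adjusted p = 0.48). The estrogen receptor Esr2 fell (-0.46 ± 0.10, adjusted p = 0.0135), and Esr1 (-0.21 ± 0.10) and Gper1 (-0.04 ± 0.09), with adjusted p = 0.223 to 0.855, did not pass. Omitting 1 array ended the call of Lmna (baseline male 2, adjusted p = 0.052), Esr2 (baseline males 1 and 2, adjusted p = 0.0517 to 0.0664), the junction list (baseline male 3, adjusted p = 0.0709), the fluid transport list (baseline male 1 or ventilated male 3, adjusted p = 0.05028 to 0.062) and the androgen list (baseline male 1 or ventilated male 1, adjusted p = 0.122 to 0.126). Leaving 1 array out moved over 1.5-fold the median of the lists matrix (ventilated males 2 and 3, 0.15 to 0.38), androgen (any baseline male or ventilated males 1 and 3, 0.019 to 0.16), junction (baseline male 3, 0.068) and fluid transport (baseline male 1, 0.11).

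Markers of several cell types fell in males. B cell markers fell (median -0.93, adjusted p = 4.11e-13 and 0.0991 by estimated correlation). 0 of 14 members rose and 12 fell (0 and 14 adjusted over the list alone), among them Cr2 (-1.13 ± 0.18) and the immunoglobulin gene Ighm (-1.36 ± 0.22). Their mean changed by -1.003 (SE 0.16, exact two-sided p = 0.1), the smallest p that 3 against 3 mice allow. T cell markers fell (median -0.25, adjusted p = 0.00158 and 0.446). 0 of 16 members rose and 2 fell (0 and 2 over the list alone), with Ccr7 (-0.82 ± 0.17). Natural killer cell markers fell (median -0.11, adjusted p = 0.0493 and 0.484). 0 of 16 members rose and 2 fell (0 and 2 over the list alone), with Klrd1 (-0.81 ± 0.15) and Gzma (-0.80 ± 0.16). Fibroblast markers fell (median -0.19, adjusted p = 0.000996 and 0.35). 0 of 17 members rose and 5 fell (1 and 5 over the list alone), with G0s2 (-1.12 ± 0.15), Dcn (-0.69 ± 0.13) and Inmt (-0.70 ± 0.13). Endothelial markers fell (median -0.13, adjusted p = 0.00449 and 0.532). 0 of 23 members rose and 4 fell (0 and 6 over the list alone), with Egfl7 (-0.62 ± 0.12) beside Tmem100. Vascular and angiogenic genes fell as a list (median -0.17, adjusted p = 0.0254 and 0.446). 1 of 26 members rose and 5 fell (2 and 9 over the list alone), with the flow-responsive factor Klf2 (-0.97 ± 0.17) and Angpt1 (-0.65 ± 0.13) below and Adm above baseline. Markers of ciliated cells fell (median -0.44, adjusted p = 2.19e-05 and 0.446). 0 of 17 members rose and 3 fell (0 and 4 over the list alone), and baseline male 3 had their highest mean, 8.52. Clock genes fell as a list (median -0.45, adjusted p = 0.0174 and 0.35). 3 of 17 members rose and 7 fell (3 and 9 over the list alone). Tef (-1.06 ± 0.14), Dbp and Per3 fell, and Nfil3 (1.63 ± 0.14), a repressor of Dbp targets, rose. Of the sex-linked genes Kdm5d (-0.11 ± 0.10), Uty (-0.20 ± 0.13) and Eif2s3y (-1.28 ± 0.59), with adjusted p = 0.22 to 0.615, did not pass. The signal of Xist, a transcript of the inactive X chromosome, which males lack, fell (-0.87 ± 0.13), and what gave it was not tested. Without 1 array the call ended for the natural killer list (baseline males 1 and 2, ventilated males 1 and 3 or any ventilated female, adjusted p = 0.0515 to 0.161), the endothelial list (baseline male 1, adjusted p = 0.0736) and the vascular list (baseline males 1 and 2 or ventilated male 1, adjusted p = 0.0551 to 0.123). Medians moved over 1.5-fold without 1 array for the lists ciliated (baseline male 3, -0.19), endothelial (baseline males 2 and 3 or ventilated male 2, -0.063 to -0.20), natural killer (ventilated males 2 and 3, -0.037 to -0.17), T cell (baseline male 1, -0.15) and vascular (baseline male 2, -0.11).

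**Figure D1:**
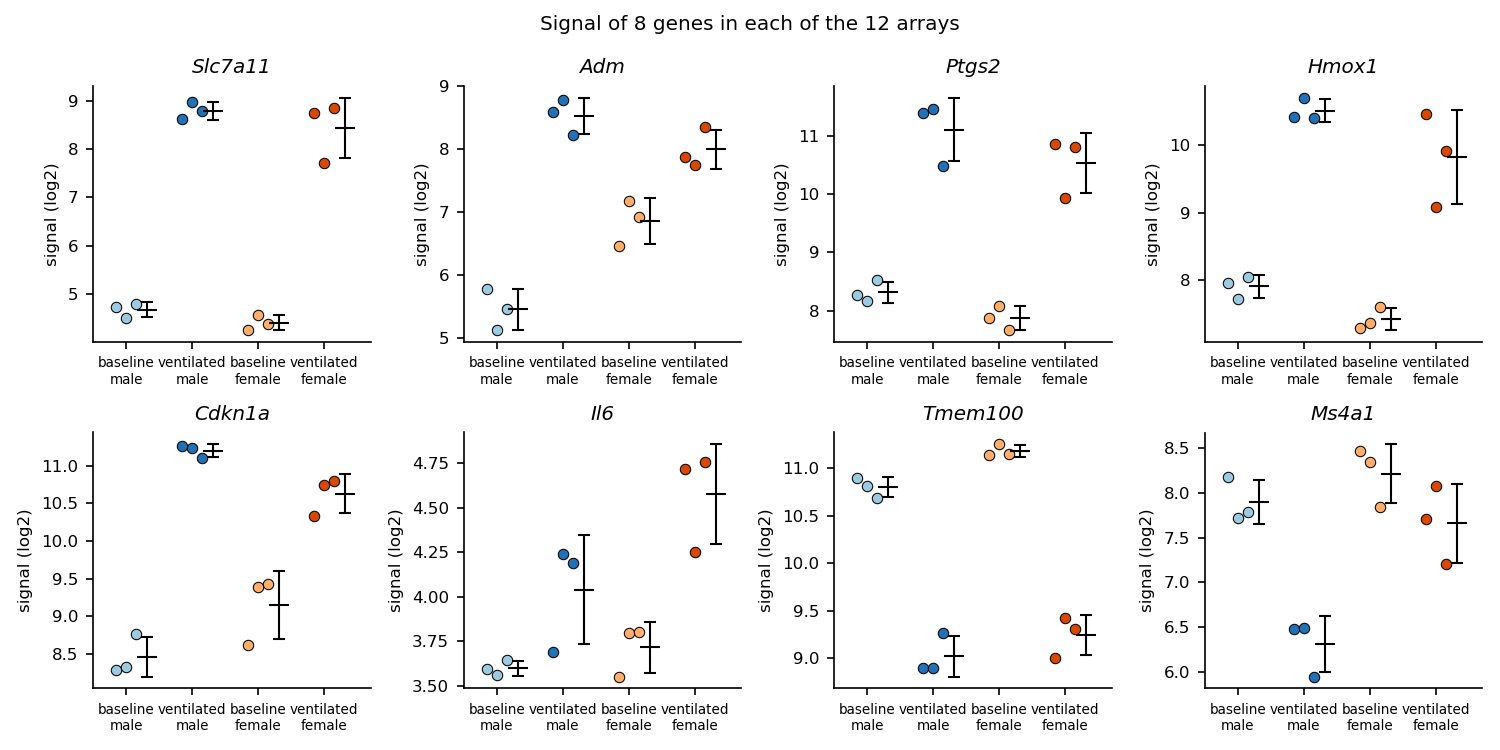
Signal (log2) of 8 genes in each of the 12 arrays, as points by group, with the mean and SD of the 3 mice beside them. Slc7a11 rose by 4.12 in males and 4.04 in females, Adm by 3.08 in males and 1.14 in females, and Ms4a1 changed by -1.58 in males and -0.56 in females.

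In females, ventilation raised Slc7a11 at least 16.5-fold (4.04 ± 0.23, adjusted p = 1.91e-06), Ptgs2 6.3-fold (2.66 ± 0.26), the metallothionein Mt2 5.89-fold (2.56 ± 0.20) and Hmox1 5.33-fold (2.41 ± 0.25). The heat shock protein gene Hspa1a rose 8.68-fold (3.12 ± 0.75, adjusted p = 0.0277), a gene with the near-identical copy Hspa1b. Tmem100 (-1.93 ± 0.12), the BMP pathway inhibitor Smad6 (-1.40 ± 0.09), the endothelial factor Sox18 (-1.44 ± 0.16) and the flow-responsive factor Klf2 (-1.50 ± 0.17) fell. The other large rises were Atf3 (2.52 ± 0.38), Pdk4 (2.25 ± 0.29), Sprr1a (2.12 ± 0.33), Eid3 (2.08 ± 0.24), Cldn4 (2.02 ± 0.24), F3 (1.95 ± 0.25) and Gclc (1.94 ± 0.15). The other large falls were Mup20 (-3.55 ± 0.73), Cyp4a14 (-1.96 ± 0.53), Meox2 (-1.50 ± 0.23) and Edn1 (-1.37 ± 0.27), and Mup3 (-2.45 ± 0.64) fell with groups that overlapped. Mup20, Mup3 and Cyp4a14 are liver genes that varied among baseline females (SD 2.02, 1.84 and 1.66). Without baseline female 2 the change of Cyp4a14 was -1.01 and that of Mup3 -1.55. In all 1174 genes changed, 640 upward and 534 downward, of which 123 at least 2-fold. In 1169 of them the groups did not overlap, as for 22.8% of all genes (chance 10%). The number was 765 without baseline female 1, 683 without baseline female 2, 751 without baseline female 3, 756 without ventilated female 1 and 481 without ventilated female 3. Removing 1 array ended the call of Hspa1a (any baseline female or ventilated females 1 and 3, adjusted p = 0.0657 to 0.125), Mup20 (ventilated female 3, adjusted p = 0.0651), Mup3 (baseline males 1 and 2, any ventilated male, baseline females 2 and 3 or ventilated females 2 and 3, adjusted p = 0.0507 to 0.164) and Cyp4a14 (any baseline male, any ventilated male or any ventilated female, adjusted p = 0.0535 to 0.159).

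The stress responses rose in females too. Glucocorticoid-responsive genes rose (median 0.56, adjusted p = 4.65e-13 and 0.0305 by estimated correlation). 12 of 23 members rose and 0 fell (15 and 1 adjusted over the list alone), with Mt1 (1.54 ± 0.17) and Fkbp5 (1.49 ± 0.19) beside Mt2 and Pdk4. NF-kB targets rose (median 0.37, adjusted p = 2.65e-12 and 0.0305). 10 of 23 members rose and 1 fell (17 and 1 over the list alone), with the NF-kB inhibitor Tnfaip3 (0.74 ± 0.08), Nfkb2 (0.86 ± 0.10) and Relb (0.76 ± 0.09). These were the 2 lists of this comparison that passed by estimated correlation. Nrf2 and oxidant defence genes rose (median 0.41, adjusted p = 8.21e-12 and 0.0663). 10 of 20 members rose and 0 fell (11 and 1 over the list alone), with the thioredoxin reductase Txnrd1 (1.47 ± 0.13). Of the unfolded protein response genes 5 of 20 members rose and 0 fell (7 and 0 over the list alone), with median 0.27, adjusted p = 7.85e-08 and 0.191, led by Atf4 (0.89 ± 0.12), Asns (0.89 ± 0.14), Sesn2 (1.11 ± 0.19) and Chac1 (1.81 ± 0.32). Immediate-early genes rose (median 0.39, adjusted p = 9.84e-06 and 0.542). 7 of 35 members rose and 1 fell (14 and 2 over the list alone), with Maff (1.45 ± 0.18) and Gadd45g (1.63 ± 0.21) above and Klf2 below baseline, and without Fos (-0.48 ± 0.33) and Egr1 (0.52 ± 0.43), with adjusted p = 0.504 to 0.591. Hypoxia and glycolysis genes rose (median 0.29, adjusted p = 2.57e-06 and 0.0663). 5 of 18 members rose and 0 fell (9 and 0 over the list alone), with Hk2 (1.15 ± 0.16) and Adm (1.14 ± 0.21). Of the p53 and senescence genes 6 of 19 members rose and 0 fell (7 and 0 over the list alone), with median 0.18, adjusted p = 0.000307 and 0.0848, and they included Plk3 (1.82 ± 0.23) and Cdkn1a (1.49 ± 0.20). Apoptosis and pyroptosis genes rose (median 0.05, adjusted p = 0.0266 and 0.191). 5 of 19 members rose and 0 fell (5 and 0 over the list alone), with Casp4 (1.01 ± 0.10) and Tnfrsf12a (1.92 ± 0.23). Heat shock genes rose (median 0.52, adjusted p = 0.000423 and 0.553). 3 of 15 members rose and 0 fell (3 and 0 over the list alone). Calls that ended without 1 array were those of the apoptosis list (baseline female 3 or ventilated female 2, adjusted p = 0.0879 to 0.129). Without 1 array medians moved over 1.5-fold for the lists apoptosis (baseline female 2 or ventilated females 1 and 2, 0.02 to 0.091) and p53 (ventilated female 2, 0.10).

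Among inflammatory genes of females, cytokines rose (median 0.24, adjusted p = 2.26e-05 and 0.0741 by estimated correlation). 3 of 22 members rose and 0 fell (7 and 0 adjusted over the list alone), with Il1r2 (1.52 ± 0.16) and Il6 (0.86 ± 0.15, adjusted p = 0.00614). Tnf (0.80 ± 0.24) and Il1b (0.05 ± 0.31), with adjusted p = 0.0742 to 0.961, did not pass. Nor did Cxcl1 (0.61 ± 0.21), Cxcl2 (0.08 ± 0.17) and Ccl2 (0.27 ± 0.18), with adjusted p = 0.122 to 0.867, nor chemokines as a list (median 0.13, adjusted p = 0.0976). Tnf passed without ventilated female 2 (adjusted p = 0.0193), Cxcl1 passed without ventilated female 2 (adjusted p = 0.00472) and the chemokine list passed without ventilated females 2 and 3 (adjusted p = 0.0118 to 0.037). Neutrophil markers rose (median 0.51, adjusted p = 3.41e-07 and 0.217). 4 of 23 members rose and 0 fell (7 and 0 over the list alone), with Clec4d (1.08 ± 0.14) and Il1f9 (1.53 ± 0.25). Acute phase and innate sensing genes rose (median 0.21, adjusted p = 0.0013 and 0.191). 4 of 25 members rose and 0 fell (6 and 1 over the list alone), with the endotoxin receptor Tlr4 (0.59 ± 0.11). Interferon-stimulated genes fell (median -0.24, adjusted p = 5.34e-05 and 0.174). 0 of 23 members rose and 5 fell (0 and 6 over the list alone), with Xaf1 (-0.72 ± 0.10). Extracellular matrix genes rose (median 0.12, adjusted p = 0.000401 and 0.211). 8 of 30 members rose and 0 fell (8 and 2 over the list alone), with Has1 (1.17 ± 0.14), Thbs1 (1.72 ± 0.22), Lox (1.06 ± 0.16) and Timp1 (0.61 ± 0.09). Of the coagulation and fibrinolysis genes 5 of 17 members rose and 1 fell (7 and 2 over the list alone), and the test pointed upward although the median was -0.01 (adjusted p = 0.0428, and adjusted p = 0.191 by estimated correlation). F3 and Plaur (1.32 ± 0.22) rose and the anticoagulant receptor Thbd (-0.67 ± 0.12) fell. Androgen-responsive genes rose (median 0.12, adjusted p = 0.00525 and 0.191). 4 of 15 members rose and 0 fell (4 and 1 over the list alone), with Zbtb16 (1.70 ± 0.23) and Slc38a2 (1.05 ± 0.16). Esr2 fell (-0.43 ± 0.10, adjusted p = 0.0276), and Esr1 (0.03 ± 0.10), Gper1 (0.0036 ± 0.09) and Lmna (0.34 ± 0.12), with adjusted p = 0.124 to 0.99, did not pass. Of the sex-linked genes Xist (0.05 ± 0.13), Kdm5d (-0.04 ± 0.10), Uty (-0.02 ± 0.13) and Eif2s3y (0.03 ± 0.59), with adjusted p = 0.883 to 0.985, did not pass. Single arrays decided the call of Esr2 (baseline females 1 and 2 or any ventilated female, adjusted p = 0.0556 to 0.115) and the coagulation list (baseline male 3, ventilated male 1, baseline females 1 and 3 or ventilated female 2, adjusted p = 0.052 to 0.0661). Leaving 1 array out moved over 1.5-fold the median of the lists acute phase (baseline female 1, 0.062), androgen (baseline female 1 or ventilated females 1 and 2, 0.054 to 0.072), matrix (baseline females 2 and 3, 0.075 to 0.20) and coagulation (any baseline female or ventilated females 1 and 2, -0.049 to 0.055).

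Endothelial markers had the lowest p of all lists in females (median -0.54, adjusted p = 3.57e-20 and 0.0741). 0 of 23 members rose and 14 fell (0 and 20 adjusted over the list alone), with Cldn5 (-0.86 ± 0.11), which seals endothelial junctions, and the angiopoietin receptor Tek (-0.70 ± 0.11) beside Tmem100 and Sox18. Vascular and angiogenic genes fell (median -0.50, adjusted p = 5.89e-13 and 0.0607). 1 of 26 members rose and 13 fell (1 and 19 over the list alone), with Ramp2 (-0.66 ± 0.12), part of the Adm receptor, and Angpt2 (-0.93 ± 0.17). Growth factor genes of the EGF, TGF-beta and Wnt families fell (median -0.13, adjusted p = 0.0046 and 0.191). 1 of 23 members rose and 6 fell (3 and 8 over the list alone), with Id1 (-1.10 ± 0.14), Smad7 (-0.66 ± 0.09) and Bmp4 (-0.85 ± 0.13) beside Smad6. Fibroblast markers fell (median -0.18, adjusted p = 0.00259 and 0.361). 0 of 17 members rose and 3 fell (0 and 7 over the list alone), with G0s2 (-0.96 ± 0.15) and Tcf21 (-1.01 ± 0.19). Natural killer cell markers fell (median -0.20, adjusted p = 0.0011 and 0.247). 0 of 16 members rose and 3 fell (0 and 3 over the list alone), with Gzma (-0.79 ± 0.16). Markers of red blood cells fell (median -0.18, adjusted p = 0.00334 and 0.0987). 0 of 8 members rose and 3 fell (0 and 3 over the list alone), with Car2 (-0.71 ± 0.13). B cell markers fell (median -0.35, adjusted p = 0.00441 and 0.542) although 0 of 14 members rose and 0 fell (0 and 0 over the list alone), and Cd79a (-0.59 ± 0.23) and Ms4a1 (-0.56 ± 0.22), with adjusted p = 0.174 to 0.191, did not pass. Club and goblet cell markers rose (median 0.41, adjusted p = 0.0241 and 0.662) although 0 of 14 members passed (0 over the list alone). Clock genes rose as a list (median 0.13, adjusted p = 0.0457 and 0.41). 5 of 17 members rose and 0 fell (5 and 2 over the list alone), with Nfil3 (1.21 ± 0.14) and Bhlhe40 (0.98 ± 0.15). Dropping 1 array ended the call of the fibroblast list (baseline female 3, adjusted p = 0.0901), the B cell list (baseline female 1 or ventilated female 3, adjusted p = 0.141 to 0.15), the club cell list (baseline female 2 or ventilated female 1, adjusted p = 0.249 to 0.258) and the clock list (baseline males 1 and 3, any ventilated male, baseline females 2 and 3 or ventilated female 1, adjusted p = 0.0505 to 0.307). Medians moved over 1.5-fold without 1 array for the lists clock (baseline female 3 or ventilated females 1 and 2, 0.00096 to 0.28), B cell (baseline female 1 or ventilated female 3, -0.16 to -0.22), club cell (ventilated female 1, 0.27) and fibroblast (baseline female 3, -0.12).

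**Figure D2:**
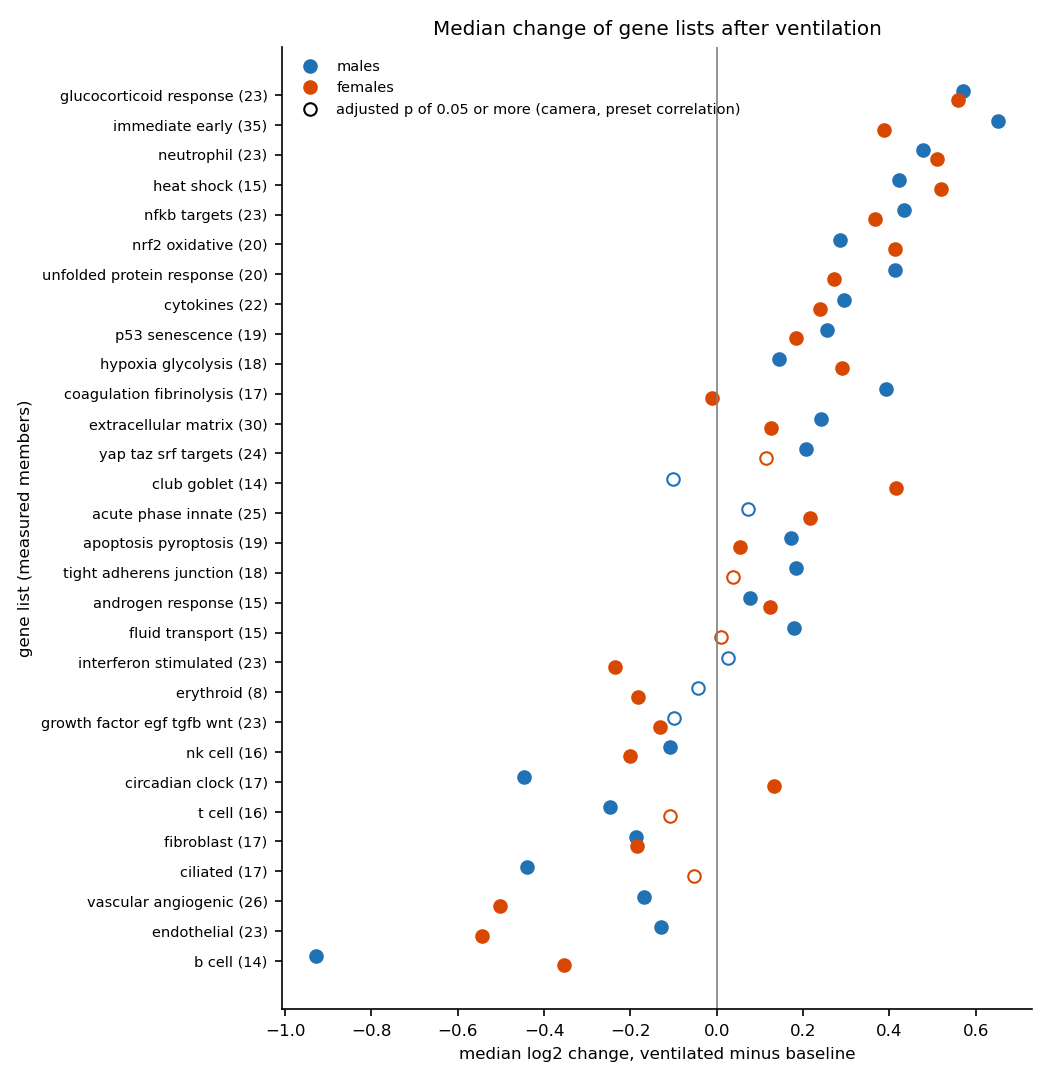
Median log2 change after ventilation of each gene list that passed in males (blue) or females (orange), with open points where the list did not pass and the number of measured members in brackets. The endothelial list lies at -0.13 in males and -0.54 in females and the B cell list at -0.93 in males and -0.35 in females.

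Over both sexes the change tested was the mean of the male and the female change. Slc7a11 rose at least 16.9-fold (4.08 ± 0.16, adjusted p = 1.76e-08), Hspa1a 7.58-fold (2.92 ± 0.53), Ptgs2 6.59-fold (2.72 ± 0.18) and the stress factor Atf3 5.91-fold (2.56 ± 0.27). The next rises were Hmox1 (2.52 ± 0.18), Mt2 (2.41 ± 0.14), Tnfrsf12a (2.35 ± 0.16), Pdk4 (2.27 ± 0.21), Cdkn1a (2.12 ± 0.14), Adm (2.11 ± 0.15), Saa3 (2.08 ± 0.22) and Sprr1a (2.06 ± 0.23). The largest falls were Tmem100 (-1.86 ± 0.09), Dbp (-1.83 ± 0.28), Per3 (-1.45 ± 0.21), Meox2 (-1.45 ± 0.16), Ifi208 (-1.43 ± 0.25), Lrrn3 (-1.32 ± 0.11) and Olfml1 (-1.25 ± 0.16). Mup20 (-1.91 ± 0.52), at background in males, passed in females only. Il6 (0.65 ± 0.11, adjusted p = 0.00132), Cxcl1 (0.73 ± 0.15) and Lmna (0.45 ± 0.08) rose and Esr2 (-0.44 ± 0.07) fell, as did the Xist signal (-0.41 ± 0.09). Mup20 (-0.27 ± 0.73) and Il6 did not pass in males, nor Dbp, Per3, Ifi208, Cxcl1, Lmna and Xist (0.05 ± 0.13) in females. Tnf (0.49 ± 0.17), Egr1 (0.83 ± 0.30) and Ccl2 (0.27 ± 0.12), with adjusted p = 0.0759 to 0.18, did not pass. Nor did Il1b (0.09 ± 0.22), Cxcl2 (-0.09 ± 0.12), Fos (0.03 ± 0.23), Esr1 (-0.09 ± 0.07) and Gper1 (-0.02 ± 0.07), with adjusted p = 0.468 to 0.962, or Kdm5d (-0.07 ± 0.07), Uty (-0.11 ± 0.09) and Eif2s3y (-0.62 ± 0.41), with adjusted p = 0.381 to 0.597. Egr1 passed without ventilated male 3 or ventilated female 2 (adjusted p = 0.0242 to 0.0321) and Tnf passed without ventilated female 2 (adjusted p = 0.0154). In all 3181 genes changed, 1798 upward and 1383 downward, of which 120 at least 2-fold. Of the 59 lists 28 passed, 18 upward and 10 downward, and 2 of them by estimated correlation: glucocorticoid-responsive genes (median 0.53, adjusted p = 1.48e-12 and 0.0327 by estimated correlation) and NF-kB targets (median 0.42, adjusted p = 1.47e-10 and 0.0327). The strongest of the other 26 were immediate-early genes (median 0.40, adjusted p = 1.11e-09), unfolded protein response genes (median 0.32, adjusted p = 1.18e-09), Nrf2 genes (median 0.25, adjusted p = 1.19e-08), neutrophil markers (median 0.65, adjusted p = 8.67e-08), endothelial markers (median -0.30, adjusted p = 2.6e-11) and B cell markers (median -0.65, adjusted p = 1.18e-09), with adjusted p = 0.0962 to 0.305 by estimated correlation. Leaving out 1 array ended the call of Mup20 (ventilated females 2 and 3, adjusted p = 0.0551 to 0.0617).

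Most genes called in 1 sex had the same sign in the other. Across 21506 genes, which are not independent replicates, the male and female changes had a Pearson r of 0.593 and a Spearman rho of 0.448. Of the genes higher after ventilation, 415 passed in both sexes where 34.7 would by chance, and of those lower 190 where 19.0 would. The sign in females was the same for 92.6% of the genes called in males, and that in males for 93.2% of the genes called in females. The female change was a median 0.558 of the male change among genes called in males, a ratio that choosing genes on the male change lowers. Likewise 86.0% of the genes called in males had a smaller change in females, and 70.8% of those called in females a smaller change in males. Only 3 genes passed in opposite directions, picked out after their values were seen. The cell cycle kinase gene Wee1 fell in males (-0.58 ± 0.15) and rose in females (0.75 ± 0.15), and Sema3f (0.26 ± 0.08 in males, -0.29 ± 0.08 in females) and Slc9a3r2 (0.42 ± 0.10 and -0.42 ± 0.10) did the reverse. At baseline Wee1 was lower and Slc9a3r2 higher in females. None of the 6 calls held in every fit without 1 array. In males they ended for Wee1 (any male, adjusted p = 0.0531 to 0.113), Sema3f (any of the 12 arrays, adjusted p = 0.056 to 0.162) and Slc9a3r2 (baseline males 1 and 3 or ventilated males 1 and 3, adjusted p = 0.0506 to 0.0699). In females they ended for Wee1 (baseline females 2 and 3 or ventilated female 3, adjusted p = 0.0521 to 0.058), Sema3f (baseline males 1 and 2, ventilated males 1 and 2, any baseline female or any ventilated female, adjusted p = 0.0508 to 0.136) and Slc9a3r2 (baseline females 2 and 3 or any ventilated female, adjusted p = 0.0671 to 0.0979).

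**Figure D3:**
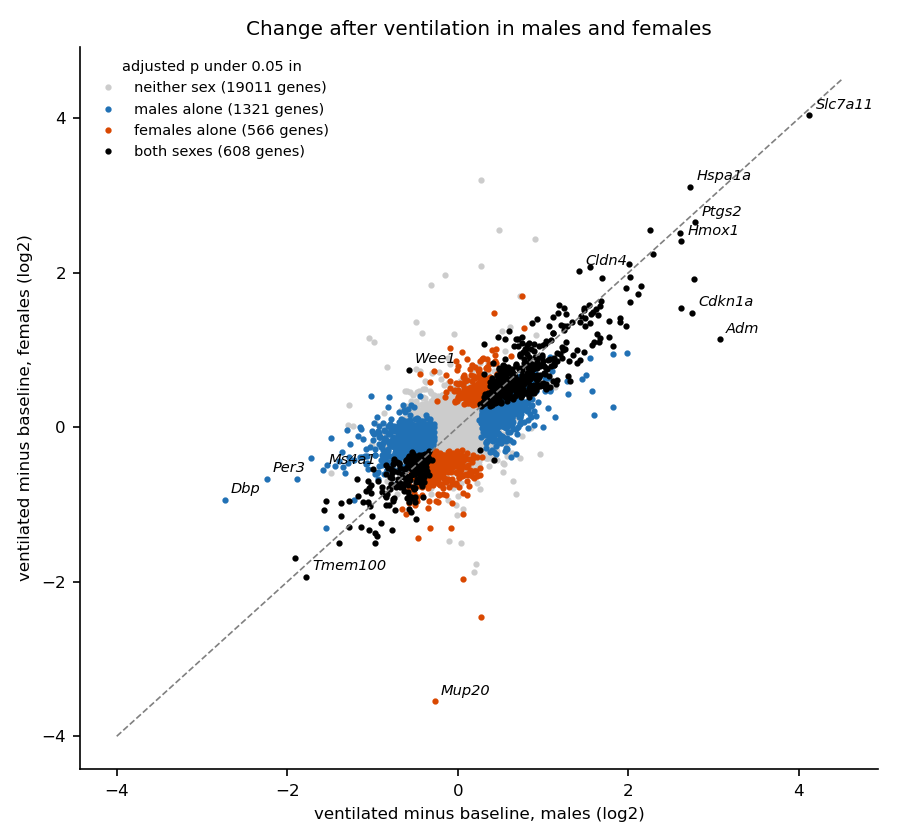
Change after ventilation (log2, ventilated minus baseline) of 21506 genes in males (horizontal) and females (vertical), coloured by the sex in which the gene passed, with the line of equal change dashed. Slc7a11 lies near the line at 4.12 and 4.04, Adm below it at 3.08 and 1.14, and Wee1 has opposite signs at -0.58 and 0.75.

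The interaction asks directly whether ventilation changed a gene differently in females and males. No gene passed with limma (0 of 21506, lowest adjusted p = 0.116), while 1832 genes had an unadjusted p under 0.05 where chance would give 1075.3. Of the genes with the lowest p, Adm differed most (-1.94 ± 0.30, adjusted p = 0.116). With it stood Ciart (1.13 ± 0.19), Wee1 (1.32 ± 0.22), Tex35 (0.77 ± 0.12), Selenok-ps1 (0.77 ± 0.13) and Ctsk (0.89 ± 0.17), with adjusted p = 0.116 to 0.171, on the side of a higher change in females, and Gata2 (-0.86 ± 0.13), Chst1 (-0.79 ± 0.13), Slc9a3r2 (-0.85 ± 0.14) and Rasl11a (-1.45 ± 0.25), with adjusted p = 0.116 to 0.12, on the side of a lower one. Cdkn1a (-1.26 ± 0.28, adjusted p = 0.215) and the Xist signal (0.93 ± 0.18, adjusted p = 0.171) did not pass. Nor did Il6 (0.42 ± 0.22), Tnf (0.64 ± 0.34), Il1b (-0.09 ± 0.43), Cxcl1 (-0.23 ± 0.30), Cxcl2 (0.34 ± 0.25) and Ccl2 (-0.01 ± 0.25), with adjusted p = 0.629 to 0.998, Fos (-1.02 ± 0.47), Egr1 (-0.62 ± 0.60) and Atf3 (-0.08 ± 0.54), with adjusted p = 0.581 to 0.979, Lmna (-0.22 ± 0.17), Esr1 (0.24 ± 0.14), Esr2 (0.03 ± 0.14) and Gper1 (0.05 ± 0.13), with adjusted p = 0.658 to 0.967, or Kdm5d (0.07 ± 0.15), Uty (0.17 ± 0.18) and Eif2s3y (1.32 ± 0.83), with adjusted p = 0.689 to 0.918. In simulations that changed 200 genes alike, 0%, 78.5% and 98.5% were found at log2 differences of 0.5, 1 and 2. Adm at -1.94 did not pass, so real differences over 0.5 can be missed too. The number was 2 without baseline female 1 or ventilated female 2. Wee1 and Rasl11a passed without baseline female 1 (adjusted p = 0.0165 and 0.0394) and Ciart without ventilated female 2 (adjusted p = 0.0484).

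Among gene lists, 15 of 59 differed between the sexes in their response with the preset correlation, 0 by estimated correlation and 0 with fry. Of 100 splits of the same arrays, 56 gave 15 lists or more. These splits exchange sex labels within each state, so sex differences enter their counts and they cannot decide. Chance was not excluded. Endothelial markers fell more in females (median -0.34, adjusted p = 3.83e-11 and 0.207 by estimated correlation), with 9 of 23 members lower adjusted over the list alone and 0 over all genes, and so did vascular genes (median -0.32, adjusted p = 7.41e-08 and 0.207). B cell markers fell less in females (median 0.66, adjusted p = 1.11e-09 and 0.207), with 5 of 14 members higher over the list alone and 0 over all genes. Clock genes went higher in females (median 0.44, adjusted p = 2.31e-06 and 0.207), with 10 members higher and 2 lower over the list alone and 0 over all genes, among them Per1 (0.91 ± 0.19). The change was also lower in females for immediate-early genes (median -0.37, adjusted p = 0.000923), growth factor genes (median -0.22, adjusted p = 0.00463), interferon-stimulated genes (median -0.18, adjusted p = 0.000181), coagulation genes (median -0.18, adjusted p = 0.0144), nuclear lamina genes (median -0.17, adjusted p = 0.0149) and red blood cell markers (median -0.20, adjusted p = 0.0181), with adjusted p = 0.207 to 0.646 by estimated correlation. It was higher in females for markers of ciliated cells (median 0.45, adjusted p = 2.04e-05), club and goblet cells (median 0.57, adjusted p = 0.000317), basal airway cells (median 0.24, adjusted p = 0.0144), adipocytes (median 0.37, adjusted p = 0.0388) and for oxidative phosphorylation genes (median 0.09, adjusted p = 0.0268), with adjusted p = 0.207 to 0.646 by estimated correlation. The ciliated difference goes with the high mean of 8.52 in baseline male 3. The call ended when a single array was left out for the immediate-early list (ventilated male 2 or ventilated female 2, adjusted p = 0.059 to 0.0645), the lamina list (baseline female 1, adjusted p = 0.106), the red blood cell list (ventilated males 1 and 2, adjusted p = 0.0541 to 0.0619) and the club cell list (baseline male 3, adjusted p = 0.0546). The same held for the basal cell list (ventilated male 3 or ventilated female 1, adjusted p = 0.0524 to 0.117), the adipocyte list (baseline male 3, ventilated males 1 and 3, baseline females 1 and 2 or ventilated females 1 and 2, adjusted p = 0.0619 to 0.406) and the oxidative phosphorylation list (baseline male 3, ventilated males 1 and 3, baseline female 2 or ventilated female 1, adjusted p = 0.0619 to 0.0987). Without both arrays that stood apart the adipocyte list turned (median -0.0541, adjusted p = 0.967). Without 1 array medians moved over 1.5-fold for the lists adipocyte (baseline males 1 and 3, baseline female 2 or ventilated female 1, 0.063 to 0.59), basal cell (ventilated female 1, 0.16), club cell (baseline male 3, 0.17) and immediate-early (ventilated male 2 or ventilated female 2, -0.24). They also moved for ciliated (baseline male 3, 0.24), coagulation (ventilated male 1, -0.12), clock (baseline female 1, 0.66), interferon (baseline female 3, -0.31), oxidative phosphorylation (baseline male 3, ventilated male 3, baseline females 2 and 3 or ventilated female 1, 0.043 to 0.16) and vascular (baseline male 3, -0.20).

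At baseline, before any ventilation, the single genes that differed between the sexes included sex-linked and clock genes. Xist was higher in females (5.61 ± 0.13, adjusted p = 1.14e-11), and the Y-linked genes Eif2s3y (-4.04 ± 0.59), Uty (-3.66 ± 0.13) and Kdm5d (-2.84 ± 0.10) were lower. With 1 sex at background, these are lower bounds in size, as are Mup20 and Mup3 below. Ddx3y was not analysed here. The clock activator Arntl was 3.78-fold higher (1.92 ± 0.28), and the genes it drives, Dbp (-1.85 ± 0.39), Per3 (-1.53 ± 0.29) and Bhlhe41 (-1.38 ± 0.27), were lower, as was Wee1 (-1.45 ± 0.15). Adm was 2.64-fold higher (1.40 ± 0.21), as were Rasl11a (1.35 ± 0.18), Prdm8 (1.32 ± 0.16), Gfra2 (1.10 ± 0.14), Slc5a12 (1.10 ± 0.17) and Spon2 (1.85 ± 0.33) and elastin, Eln (1.77 ± 0.33). The small RNA Rny1 was lower (-1.37 ± 0.21). The liver transcripts Alb (3.57 ± 0.65), Mup20 (4.17 ± 0.73) and Mup3 (3.39 ± 0.64) were higher in females. In all 543 genes differed, 380 higher and 163 lower in females, of which 62 at least 2-fold, 16 higher and 46 lower. In all 543 the groups did not overlap, as for 21.2% of all genes (chance 10%). The number was 217 without baseline male 2, 273 without baseline male 3, 244 without baseline female 2 and 230 without baseline female 3, and 150 without both arrays that stood apart. The share higher, 70.0%, was 54.8% after quantile normalization. A single omitted array ended the call of Dbp (any baseline male or baseline females 2 and 3, adjusted p = 0.052 to 0.0956), Per3 (baseline male 2 or baseline females 2 and 3, adjusted p = 0.0615 to 0.0638), Bhlhe41 (baseline males 1 and 2 or baseline female 3, adjusted p = 0.0529 to 0.0608), Spon2 (baseline female 3, adjusted p = 0.05037), Eln (baseline male 2 or baseline females 2 and 3, adjusted p = 0.0572 to 0.0592) and Mup3 (baseline male 2 or baseline female 3, adjusted p = 0.053 to 0.0578). Leaving 1 array out moved over 1.5-fold the median of the matrix list (baseline female 1, 0.14).

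Of the lists, 27 of 59 differed at baseline, 16 higher and 11 lower in females. Genes that escape X inactivation were higher (median 0.42, adjusted p = 1.27e-10 and 0.0134 by estimated correlation). 4 of 9 members were higher and 0 were lower (7 and 0 adjusted over the list alone), with Kdm6a (0.84 ± 0.08) and Kdm5c (0.54 ± 0.08), and Y-linked genes lower (median -1.49, adjusted p = 2.6e-07 and 0.0134). These were the 2 lists that passed by estimated correlation. Endothelial markers were higher in females (median 0.39, adjusted p = 1.18e-12 and 0.163). 8 of 23 members were higher and 0 were lower (19 and 0 over the list alone), with Eng (0.60 ± 0.10). Their mean differed by 0.42 (SE 0.09, exact two-sided p = 0.1). Vascular genes were higher (median 0.37, adjusted p = 3.44e-09 and 0.118). 7 of 26 members were higher and 0 were lower (16 and 0 over the list alone), with the lymphatic growth factor Vegfc (0.70 ± 0.13). Smooth muscle and pericyte markers were higher (median 0.39, adjusted p = 1.72e-07 and 0.125). 4 of 17 members were higher and 0 were lower (8 and 0 over the list alone), with Pdgfrb (1.00 ± 0.14). Clock genes were lower as a list (median -0.66, adjusted p = 2.05e-07 and 0.102). 2 of 17 members were higher and 10 were lower (3 and 11 over the list alone), with Ciart (-1.20 ± 0.13), Per1 (-1.02 ± 0.13) and Cry2 (-0.66 ± 0.11). The Dbp limb minus the Arntl limb had a sex difference of -2.33 (SE 0.53, exact two-sided p = 0.1, the smallest possible). Glucocorticoid-responsive genes were lower (median -0.24, adjusted p = 0.000522 and 0.163). 0 of 23 members were higher and 3 were lower (2 and 10 over the list alone). Of the Nrf2 and oxidant defence genes 1 of 20 members were higher and 3 were lower (2 and 8 over the list alone), with median -0.27, adjusted p = 2.15e-05 and 0.172, Nqo1 (-0.70 ± 0.09) lower and the extracellular superoxide dismutase Sod3 (0.88 ± 0.11) higher. Interferon-stimulated genes were higher (median 0.21, adjusted p = 8.17e-06 and 0.143). 3 of 23 members were higher and 0 were lower (7 and 0 over the list alone), with Oas2 (0.69 ± 0.11) and Rsad2 (0.76 ± 0.13). Extracellular matrix genes were higher (median 0.22, adjusted p = 0.00057 and 0.228). 4 of 30 members were higher and 0 were lower (6 and 1 over the list alone), with Loxl1 (0.96 ± 0.14) and Mmp14 (0.84 ± 0.12).

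Leukocyte adhesion genes were higher in baseline females (median 0.28, adjusted p = 0.000663 and 0.267 by estimated correlation). 2 of 18 members were higher and 0 were lower (6 and 0 adjusted over the list alone), with Jam2 (0.56 ± 0.10). Markers of natural killer cells (median 0.48, adjusted p = 3.91e-07), T cells (median 0.27, adjusted p = 0.000303), monocytes and interstitial macrophages (median 0.24, adjusted p = 0.0125) and fibroblasts (median 0.32, adjusted p = 0.00972) were higher too, with adjusted p = 0.14 to 0.465 by estimated correlation. So were genes of growth factors (median 0.18, adjusted p = 0.00264), the nuclear lamina (median 0.19, adjusted p = 0.00556), coagulation (median 0.11, adjusted p = 0.0306), apoptosis (median 0.14, adjusted p = 0.0355) and YAP, TAZ and SRF targets (median 0.16, adjusted p = 0.0361), with adjusted p = 0.14 to 0.545 by estimated correlation. Lower in females were heat shock genes (median -0.39, adjusted p = 0.000318), ciliated cell markers (median -0.13, adjusted p = 0.00707), alveolar type 1 markers (median -0.21, adjusted p = 0.00063), ribosomal protein genes (median -0.15, adjusted p = 0.00241), oxidative phosphorylation genes (median -0.06, adjusted p = 0.0141), platelet markers (median -0.09, adjusted p = 0.0362) and unfolded protein response genes (median -0.10, adjusted p = 0.0417), with adjusted p = 0.163 to 0.661 by estimated correlation, the first 2 beside the high means of baseline male 3. None of Il6 (0.12 ± 0.15), Il1b (0.42 ± 0.31), Tnf (-0.19 ± 0.24), Cxcl1 (0.0026 ± 0.21), Cxcl2 (-0.14 ± 0.17) and Ccl2 (-0.17 ± 0.18), with adjusted p = 0.556 to 0.997, passed at baseline. Neither did Fos (0.50 ± 0.33), Egr1 (0.25 ± 0.43), Atf3 (-0.81 ± 0.38), Cdkn1a (0.69 ± 0.20) and Lmna (-0.03 ± 0.12), with adjusted p = 0.0916 to 0.921. Nor did the receptors Esr1 (-0.04 ± 0.10), Esr2 (-0.09 ± 0.10) and Gper1 (-0.21 ± 0.09), with adjusted p = 0.27 to 0.873. Cdkn1a passed without baseline female 1 (adjusted p = 0.0154). Omitting 1 array ended the call of the monocyte list (baseline male 3, adjusted p = 0.18), the fibroblast list (baseline female 3, adjusted p = 0.108), the coagulation list (baseline male 2 or baseline females 2 and 3, adjusted p = 0.053 to 0.0915) and the apoptosis list (baseline male 1 or baseline females 1 and 2, adjusted p = 0.0698 to 0.112). It also ended for the YAP list (baseline males 1 and 2, ventilated male 3 or baseline female 1, adjusted p = 0.0516 to 0.124), the heat shock list (baseline male 3, adjusted p = 0.265), the ciliated list (baseline male 3 or baseline female 2, adjusted p = 0.127 to 0.936) and the oxidative phosphorylation list (baseline male 3 or baseline female 2, adjusted p = 0.0614 to 0.0948). The same held for the platelet list (baseline males 1 and 2 or baseline female 1, adjusted p = 0.0743 to 0.5) and the unfolded protein list (baseline male 3, baseline female 1 or ventilated female 1, adjusted p = 0.0507 to 0.738). Without both arrays that stood apart the ciliated list turned (median 0.16, adjusted p = 0.373). Medians moved over 1.5-fold without 1 array for the lists alveolar type 1 (baseline male 1, -0.12), apoptosis (baseline female 3, 0.21), ciliated (baseline males 1 and 3 or baseline female 3, -0.35 to 0.074) and coagulation (baseline males 1 and 3 or baseline females 2 and 3, 0.029 to 0.20). They also moved for heat shock (baseline males 1 and 3, -0.16 to -0.59), adhesion (baseline male 3, 0.16), oxidative phosphorylation (baseline male 3 or baseline female 3, -0.029 to -0.10), platelet (baseline males 1 and 3, -0.028 to -0.21) and unfolded protein (baseline males 1 and 3 or baseline female 1, -0.032 to -0.17).

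**Figure D4:**
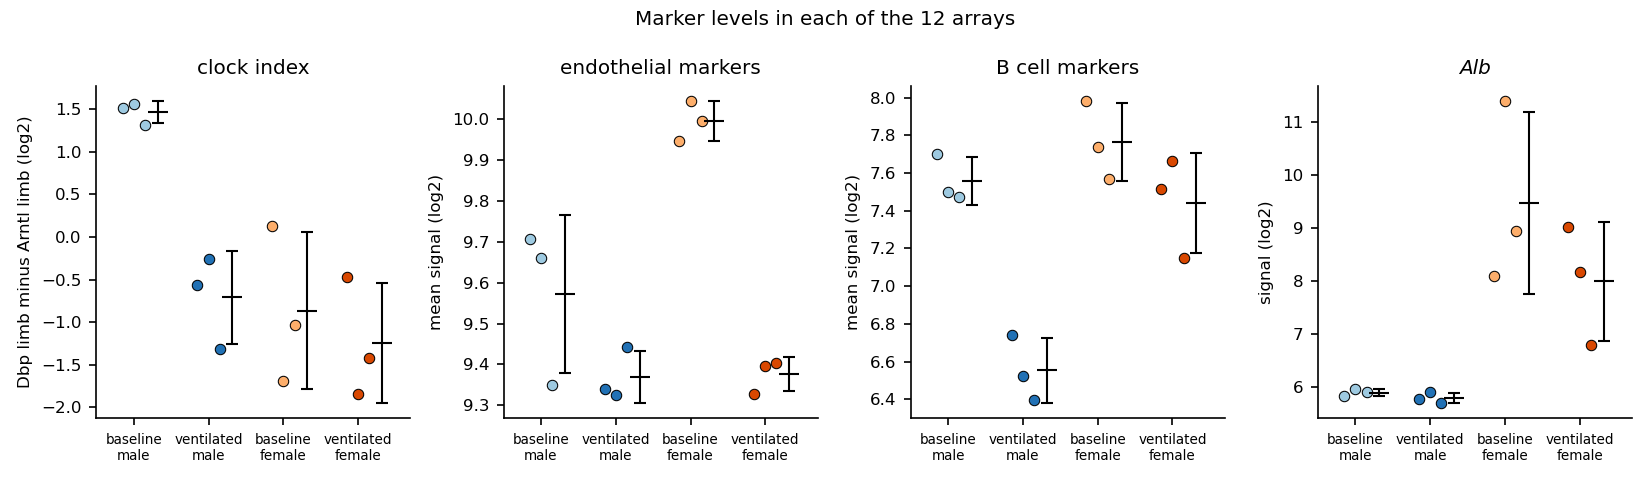
Clock index (Dbp limb minus Arntl limb), mean signal of 23 endothelial and 14 B cell markers, and signal of Alb, all log2, in each of the 12 arrays, with the mean and SD per group. The 3 baseline males have the 3 highest clock indices (1.32 to 1.56), and Alb reaches 11.4 in baseline female 2 against 5.71 to 5.96 in the 6 male arrays.

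After ventilation, the single genes higher in females included genes of B and T cells, in calls that rest on single arrays. Ms4a1 was 2.54-fold higher (1.35 ± 0.22, adjusted p = 0.0189), the B cell receptor chain Cd79a 2.51-fold (1.33 ± 0.23) and the kinase Blk 2.04-fold (1.02 ± 0.16). Bank1 (1.12 ± 0.21), Cr2 (0.89 ± 0.18), Stap1 (1.09 ± 0.18), Slamf6 (1.01 ± 0.17), Lbh (0.95 ± 0.13), Stat4 (0.93 ± 0.18) and Cd3g (0.92 ± 0.18) were higher as well, as was the retinol enzyme Lrat (1.51 ± 0.29). Against background, Xist was higher (6.53 ± 0.13), and Uty (-3.49 ± 0.13) and Kdm5d (-2.77 ± 0.10) were lower. Eif2s3y (-2.73 ± 0.59, adjusted p = 0.0556) did not pass. Eif2s3y passed without ventilated male 1 (adjusted p = 3.47e-06). Igfbp2 (-0.98 ± 0.18), Bcar3 (-0.91 ± 0.15), Rgcc (-0.80 ± 0.15), C2cd4b (-0.79 ± 0.13) and Scel (-0.76 ± 0.14) were lower in females, as was Rny1 (-1.03 ± 0.21, adjusted p = 0.04999). In all 125 genes differed, 70 higher and 55 lower in females, of which 28 at least 2-fold, and in all 125 the groups did not overlap, as for 20.7% of all genes (chance 10%). The number was 68 without baseline male 2, 204 without baseline male 3, 56 without ventilated male 1, 12 without ventilated male 2, 242 without ventilated male 3, 217 without ventilated female 1, 17 without ventilated female 2 and 36 without ventilated female 3. The share higher, 56.0%, was 40.2% after quantile normalization and 34.7% after median centring. Every call named here other than those of Xist, Uty and Kdm5d ended without ventilated male 2 and also without ventilated female 2, and some ended without baseline males 1 and 2, ventilated males 1 and 3, baseline females 2 and 3 or ventilated females 1 and 3 (adjusted p = 0.0505 to 0.205 where a call ended).

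Of the lists, 19 of 59 differed after ventilation, 12 higher and 7 lower in females (5 with fry and 2 by estimated correlation). The 2 were genes escaping X inactivation (median 0.44, adjusted p = 2.46e-12 and 0.0133) and Y-linked genes (median -1.45, adjusted p = 3.46e-07 and 0.0142). Of 10 splits 3, the real one included, gave 19 or more, so chance is not excluded for the count. B cell markers were higher (median 0.91, adjusted p = 3.55e-15 and 0.162). 5 of 14 members were higher and 0 were lower (14 and 0 adjusted over the list alone). Their mean differed by 0.89 (SE 0.16, exact two-sided p = 0.1). Markers of T cells (median 0.41, adjusted p = 1.0e-08), natural killer cells (median 0.23, adjusted p = 2.51e-05), smooth muscle and pericytes (median 0.24, adjusted p = 8.2e-05), fibroblasts (median 0.28, adjusted p = 0.00149), cardiac muscle (median 1.01, adjusted p = 0.00201), complement (median 0.15, adjusted p = 0.0235), adipocytes (median 0.33, adjusted p = 0.0323), dendritic cells (median 0.23, adjusted p = 0.0327), club and goblet cells (median 0.46, adjusted p = 0.0372) and ciliated cells (median 0.21, adjusted p = 0.0415) were higher in females as well, with adjusted p = 0.236 to 0.733 by estimated correlation, and of the cardiac and adipocyte markers 0 of 17 and 0 of 14 passed singly. Alveolar type 1 markers were lower in females (median -0.26, adjusted p = 3.13e-07 and 0.236). 0 of 15 members were higher and 3 were lower (0 and 8 over the list alone). Also lower were immediate-early genes (median -0.27, adjusted p = 3.13e-07), heat shock genes (median -0.50, adjusted p = 6.16e-05), glucocorticoid-responsive genes (median -0.25, adjusted p = 0.000154), unfolded protein response genes (median -0.23, adjusted p = 0.00019) and fluid transport genes (median -0.13, adjusted p = 0.048), with adjusted p = 0.236 to 0.55 by estimated correlation. Endothelial markers did not differ by the test (median -0.00046, adjusted p = 0.947), with a mean difference of 0.01 (SE 0.09, exact two-sided p = 0.9). None of Il6 (0.54 ± 0.15), Il1b (0.33 ± 0.31), Tnf (0.45 ± 0.24), Cxcl1 (-0.23 ± 0.21), Cxcl2 (0.20 ± 0.17) and Ccl2 (-0.18 ± 0.18), with adjusted p = 0.121 to 0.675, passed. Neither did Fos (-0.52 ± 0.33), Egr1 (-0.38 ± 0.43), Atf3 (-0.89 ± 0.38), Cdkn1a (-0.57 ± 0.20) and Lmna (-0.25 ± 0.12), with adjusted p = 0.179 to 0.72, nor Esr1 (0.20 ± 0.10), Esr2 (-0.06 ± 0.10) and Gper1 (-0.17 ± 0.09), with adjusted p = 0.333 to 0.829. Atf3 passed without ventilated male 3 (adjusted p = 0.0465). Without 1 array the call ended for the dendritic list (ventilated male 2, adjusted p = 0.0714), the club cell list (ventilated males 1 and 3 or ventilated female 1, adjusted p = 0.0802 to 0.444), the ciliated list (ventilated males 1 and 3 or ventilated female 1, adjusted p = 0.0805 to 0.506) and the complement list (ventilated male 2 or ventilated female 2, adjusted p = 0.0538 to 0.129). It also ended for the cardiac list (ventilated female 1, adjusted p = 0.28), the adipocyte list (ventilated male 3 or ventilated female 1, adjusted p = 0.135 to 0.35) and the fluid transport list (baseline male 3, ventilated males 1 and 3 or ventilated female 1, adjusted p = 0.05001 to 0.252). Without 1 array medians moved over 1.5-fold for the lists adipocyte (ventilated female 1, 0.19), cardiac (ventilated female 1, 0.52), club cell (ventilated female 1, 0.29) and ciliated (ventilated males 1 and 2, 0.11 to 0.32). They also moved for fibroblast (ventilated male 1, 0.17), glucocorticoid (ventilated male 2, -0.16), heat shock (ventilated female 2, -0.33) and immediate-early (ventilated males 2 and 3 or ventilated female 1, -0.18 to -0.47).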

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

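The tests of the 3 explanations for the clock genes, of a steady sex difference in liver transcripts and of the endothelial cell share were chosen after the result was seen.

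The response to ventilation differed between the sexes for 15 gene lists by the interaction with the preset correlation, and for 0 of 59 with an estimated correlation and 0 with fry. As female minus male medians, it was lower for endothelial markers (-0.34), vascular genes (-0.32), immediate-early genes (-0.37), growth factor genes (-0.22), red blood cell markers (-0.20), interferon-stimulated genes (-0.18), coagulation genes (-0.18) and nuclear lamina genes (-0.17). It was higher for B cell (0.66), club and goblet cell (0.57), ciliated cell (0.45), adipocyte (0.37) and basal airway cell markers (0.24), clock genes (0.44) and oxidative phosphorylation genes (0.093). Chance is not excluded for them, since 56 of 100 splits of the arrays into groups of the same sizes gave 15 lists or more, with 30 as the highest other. For single genes limma called 0 (1832 at an unadjusted p under 0.05), a count that all 100 splits reach by construction. In 1 split 477 genes were called. A split that keeps sex in 1 state and mostly exchanges it in the other tests the sex difference instead. Whether this gave the 477 genes was not tested. Among the 2733 probe sets without a single gene symbol, which the comparisons do not use, 175 were higher and 150 lower after ventilation over both sexes, with changes from -1.63 to 2.68.

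The clock genes of the baseline males stood apart, with a clock index (Dbp limb minus Arntl limb, log2) of 1.32 to 1.56 against -1.85 to 0.127 in the 9 other arrays. Both limbs were displaced in opposite directions between the baseline groups, by -1.03 (SE 0.23, exact two-sided p = 0.1) and 1.30 (SE 0.31, exact two-sided p = 0.1), and the index by -2.33 (SE 0.53, exact p = 0.1, the smallest possible). Another time of day at sampling is a candidate explanation that cannot be told apart from the groups, as the labels give no sampling time. A fixed sex difference would leave the ventilated groups as far apart, where the index differed by -0.54 (SE 0.53, exact p = 0.3), and ventilation acting alike on both sexes would give equal changes, where they differed by 1.79 (SE 0.74, exact p = 0.185 over 400 splits). The 400 splits exchanged sex labels within each state, so the baseline sex difference is part of their spread, and the p of 0.185 cannot decide. Neither explanation is excluded.

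Liver transcripts were high in baseline females. Alb read 8.09, 11.39 and 8.93 there, 6.80 to 9.01 in ventilated females and 5.83 to 5.96 in baseline males. Carry-over of liver tissue or RNA may contribute: of 33 liver markers not looked at before, 87.9% (29) were higher in the array with most Alb than in every baseline male, where chance gives 25%, and their median difference between the sexes was 0.26. As a set they passed with the preset correlation (p = 0.000234) and not with an estimated one (p = 0.338), and 0 passed singly in limma. Whether lung makes them was not tested. A steady difference between the sexes cannot be told apart from carry-over. The marker index varied 4.17 times as much among baseline females as among baseline males, with a range of 0.83 against a mean difference of 0.37, but the male index of 4.82 lies under the median gene (6.03), where spread is that of dim probe sets. Baseline female 2 alone, at 5.67 against 4.84 and 5.06, sets the range.

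Endothelial markers fell in ventilated females by a median of -0.54 over 23 genes, from -1.93 to -0.17. A lower endothelial cell share alone would make them fall alike only if all marked the same cells and no others, which was not tested. Their changes differed by more than their errors (Cochran's Q 225.7, 95% limit 33.9), which cannot decide. Compression of bright probe sets may give part of that spread, as brighter markers fell less (rho = 0.545 across genes). About that trend Q was 190.6 (limit 32.7). A lower share as part of the fall was not tested. The sex difference of this fall, -0.42 (SE 0.12, exact p = 0.06), followed a mean that was 0.42 higher in baseline females and 0.01 higher in ventilated females.

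Over both sexes 1 of 100 splits reached the 3181 genes (the real one, highest other 468), which argues against chance. The 28 lists were reached by 3 (highest other 30), so their count says little about single lists. Within a sex or between 2 groups, 10 splits are too few for a share under 0.05. The real counts and the highest others were 1929 and 1 genes in males, 1174 and 0 in females, 543 and 0 at baseline and 125 and 0 after ventilation, and for lists 25 and 23, 25 and 20, 27 and 24, and 19 and 20.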

How the results depend on the processing

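Leaving out the 2 arrays that stand apart was chosen after the data were seen, and all other alternatives before. Of the 242 named gene results that passed, 124 passed under every alternative, and of the 119 named list results 82 passed in every fit without 1 array and 8 under every alternative. The estimated correlation left 0 lists in males, 2 in females, 2 over both sexes, 0 for the interaction, 2 at baseline and 2 after ventilation, and fry called 0, 17 and 5 for the last 3. A minimum of 2-fold, stricter by construction, left 175 genes in males, 123 in females, 120 over both sexes, 62 at baseline and 28 after ventilation. Array weights gave 943 genes at baseline and 360 after ventilation, every probe set gave 218 after ventilation, and only the 2 groups compared, with fewer arrays, 243 at baseline. Without the 2 arrays that stand apart, 150 genes differed at baseline, the correlation of the sexes was 0.637, and the adipocyte list in the interaction (median -0.0541, adjusted p = 0.967) and the ciliated list at baseline (median 0.16, adjusted p = 0.373) reversed. The cause of these changes was not tested.

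Leaving out 1 array gave 1037 to 1931 genes in males, 481 to 1254 in females, 2456 to 3216 over both sexes, 0 to 2 for the interaction, 217 to 546 at baseline and 12 to 242 after ventilation, and a correlation of the sexes of 0.518 to 0.647. Quantile normalization gave a share of higher genes of 54.8% in place of 70.0% at baseline and 40.2% in place of 56.0% after ventilation, where median centring gave 34.7%, so these shares rest on the scaling. The replicate block gave 1658 genes in males, 968 in females, 2965 over both sexes, 1 for the interaction, 434 at baseline and 122 after ventilation. The numbers do not pair the mice: after removal of the group means, 3 of 18 pairs with the same number correlated above 0.1 and 12 of 36 with different numbers. Signal over background limits low genes: the Y-linked genes Kdm5d, Uty and Eif2s3y read 4.04, 4.02 and 3.65 in baseline females, which lack them, and the lower quartiles of the arrays lay at 4.35 to 4.43.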

Other observations

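The genes named here were chosen after their values were seen, and no test was.

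Lists that did not pass over both sexes held members that moved. Among eicosanoid and arginine enzymes, beside Ptgs2, Arg2 rose (1.11 ± 0.13) and Hpgd, which breaks prostaglandins down, fell (-0.54 ± 0.10), in a list with median 0.02, adjusted p = 0.691. Of the surfactant and lipid genes (median 0.04, adjusted p = 0.146), the sterol enzymes Hmgcs1 (0.67 ± 0.08) and Sqle (0.52 ± 0.09), Pcyt1a, which makes phosphatidylcholine (0.34 ± 0.07), and the surfactant protein Sftpd (0.30 ± 0.08) rose. Among chemokines, with median 0.11, adjusted p = 0.106, Cxcl16 (0.59 ± 0.07) and Ccl17 (1.11 ± 0.17) rose and Cxcl12 (-0.47 ± 0.08) fell. The chemokine list passed without ventilated female 2 (adjusted p = 0.0302), the surfactant and lipid list passed without ventilated male 2 or ventilated female 3 (adjusted p = 0.016 to 0.0452) and the mitosis list passed without ventilated female 1 (adjusted p = 0.0331). The mesothelial and epithelial keratin Krt19 (1.12 ± 0.13) and the protease Ctsk (0.42 ± 0.08, with -0.03 ± 0.12 in males) rose, and Rtkn2 of alveolar type 1 cells (-0.95 ± 0.09) and the mast cell receptor Kit (-0.55 ± 0.10) fell. Of the mitosis genes (median 0.02, adjusted p = 0.251), Ccnb2 (0.39 ± 0.08) and Pcna (0.30 ± 0.06) rose. Ctsk, Hpgd, Kit, Ccnb2 and Cxcl12 did not pass in males alone, Pcyt1a in females alone, and Pcna and Sftpd in either sex alone. Alveolar type 2 markers did not pass (median 0.04, adjusted p = 0.908), nor did alveolar macrophage markers (median -0.13, adjusted p = 0.773).

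The Y-linked gene Eif2s3y read 4.37 in ventilated male 1, while Uty read 7.42 and Kdm5d 6.81 there, as in the other males. The Mup genes, and Hspa1a with Hspa1b, are near-identical copies whose probe sets were not separated here.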
